A study of Xenopus tropicalis with 16 samples.

How the data were processed

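Gene expression was measured on 16 single-colour Agilent microarrays of embryos of the western clawed frog, Xenopus (Silurana) tropicalis. Sample groups were taken from the sample labels: 5 control arrays (0 ppm sodium arsenate), 5 low-dose arrays (0.5 ppm) and 6 high-dose arrays (1 ppm), with an exposure of 3 days per the labels. Replicate numbers also come from the labels and run with gaps, so that a number identifies an array within its group. Nothing in the labels says that the arrays came from separate clutches or tanks, and p-values then measure only the spread between these samples, which may be technical. Total RNA was extracted with a column kit, checked by spectrophotometer and Bioanalyzer, labelled with Cy3 and hybridised by the manufacturer's one-colour protocol, per the labels' protocols. Arrays sat on 4 slides that were scanned separately, and each slide held arrays of all 3 groups.

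The scanner files hold spot intensities that the authors extracted with Agilent Feature Extraction 10.7.1.1, per the file headers. The deposited intensity used here, the processed signal, is background-subtracted and linear, and it was not normalized between arrays. The deposited value table of the series holds log2 values with a floor of 2.5 and medians of 5.83 to 5.87 per array. Between 11.1% and 14.1% of its values lie at the floor. Set against the scanner values of the same array, its columns correlated across probes with r of at least 0.994, and differences between arrays correlated with r of 0.929 to 0.999. Its scale and direction are therefore settled, while the normalization and centring behind it are not given in the sources used here. That table was used only as an alternative.

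Of 45220 spots, 43803 were not control spots, and these belong to 32899 probes. Spots marked by the scanner software as outliers (2 to 61 per array) were set to missing, spots of the same probe were averaged on the log2 scale, and no spot was saturated on any array. The values analysed are log2 of the processed signal minus the 75th percentile of that array. A probe was tested when it was well above background on at least 5 of the 16 arrays, whatever their group, which left 26345 probes. Probe identifiers carry the word specific (17780 probes) or xhyb (15119 probes), whose meaning the files do not define; the word is given for named genes of the xhyb kind. Probes were named through their sequence accession in the table of genes of the UCB_Xtro_10.0 assembly, which gave 5891 probes 1 symbol and 27008 none. The array design refers to another build, so no coordinates are given. Informative symbols covered 4872 probes and 4639 genes, of which 3977 genes were tested, each through its probe with the highest mean signal.

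Tests were made per probe with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group over all 16 arrays, contrasts, eBayes, two-sided) with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. The contrasts were low minus control, high minus control and high minus low, and a separate fit gave the slope per ppm. A comparison of the mean of both doses with the controls was added after the data were seen. The 38 gene lists were fixed before the data were examined, and 19 had at least 5 measured members. Measured members were few, such as 5 of 39 listed antioxidant and 9 of 32 listed unfolded protein genes, so list results cover those members alone. Lists not tested included arsenic uptake, export and methylation (2 measured), glutathione S-transferases and conjugation (1) and oxidative phosphorylation (4). The 19 lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Genes to be named were fixed before the data were examined as the 12 highest and 12 lowest fold changes past the threshold per contrast, up to 4 members per list past the threshold, and, where nothing passed, the 5 smallest p in each direction as not passing. The indicator genes hmox1, nqo1, gclm, as3mt, mt4, hspa5 and cyp1a1 were to be named whatever their test, and hmox1 and hspa5 were measured. Because so few probes passed, genes up to the 12 smallest p per direction were also named against control, and called probes without a symbol or not representing their gene; these were chosen after their values were seen.

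Where a probe was not well above background on any array of a group, the difference is given as a bound, with each array of that group at the higher of its own signal and the lowest signal among probes well above background. Group means of brightness and of array scores were compared with exact two-sided permutation tests, and relations across arrays with 100000 permutations. Figures were drawn with matplotlib 3.10.9. The tests were checked on simulated data drawn from the spread of these arrays, with 200 changed among 26255 probes in each of 20 runs of the high against control comparison. A median of 36.6% of 2-fold changes was found (20.9 to 76.1% over runs), 85.1% of 4-fold changes (70.1 to 95.5%) and 97.0% of 8-fold changes (92.4 to 100%). With no change simulated, 19 of 20 runs gave no call and the remaining run gave 7535. A simulated 2-fold shift of every member of a single list was found in 20 of 20 runs, and no list was called in 18 of 20 unchanged runs. Smaller list shifts, such as those of the real lists, were not simulated. The number of arrays limits the precision of every comparison.

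Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile and median normalization, the deposited value table, other filters on dim probes, marked spots kept, slide as a fixed or random block, array position as a block, the replicate number as a block with and without slide, eBayes with trend and robust, array weights, fits of only the groups compared, other thresholds, a single probe per gene, other list tests, and each array left out in turn. The mean signal column planned for normexp was not used here, since the scanner tables analysed carry the median signal, which took its place together with the median background. Array brightness as a covariate, control replicates 5 and 9 left out together, control replicate 5 left out with brightness as a covariate, and probes named specific alone were added after the data were seen. Probes without a symbol enter every count and are not named, apart from a pair of called ones given by their accession.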

Results

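The arrays profiled RNA of X. tropicalis embryos kept for 3 days in water with sodium arsenate, a salt of pentavalent inorganic arsenic, at 0.5 ppm (low, n = 5) or 1 ppm (high, n = 6), beside unexposed controls (n = 5). The labels give a single developmental interval for all arrays, and the stage of each sample is not given in the sources used here. Raw brightness differed widely: the 75th percentile of the processed signal ran from 60.4 on control replicate 9 to 624 on control replicate 5, with group means of 233 ± 225 in controls, 374 ± 117 at the low dose and 235 ± 110 at the high dose (SD). Between 66.7% and 77.8% of spots were well above background. After scaling, arrays of a group correlated across probes with r of 0.80 to 0.97 in controls, 0.90 to 0.99 at the low dose and 0.92 to 0.99 at the high dose, and no pair was near identical.

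Lens crystallin genes, the digestive enzyme gene cpa1, the lipoprotein gene apob and the gut genes enpep and fabp6 varied together across single arrays, at the high end of an axis that held 60.1% of the variance between arrays. Other genes, such as ttc27 (r = 0.94 with the axis score) and syncrip (0.93), lay at the same end. The low end held otud3 (r = -0.95), shd (-0.92) and fosl1 (-0.64), among others. The mean log2 signal of 28 crystallin probes was 0.46 ± 1.31 in controls, 1.95 ± 1.98 at the low dose and 1.30 ± 0.96 at the high dose (SD), with single arrays from -0.98 (low replicate 7) to 4.46 (low replicate 6). Differences between groups were within the spread of arrays (exact two-sided permutation p = 0.246 for low against control and 0.232 for high against control, adjusted p = 0.498 for each over 12 such tests). Scores on the axis followed log2 brightness over the 16 arrays with Pearson's r of 0.92 and Spearman's rho of 0.95 (permutation p = 1e-05 for each, the smallest that the permutations can give, adjusted p = 3e-05 over 3 relations). The value of r was 0.87 without control replicates 9 and 5, 0.92 within slides and 0.93 within groups. Neither brightness nor the axis score differed between groups by more than the spread of arrays (exact permutation p of 0.080 to 0.580, all adjusted p at least 0.498).

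**Figure D1:**
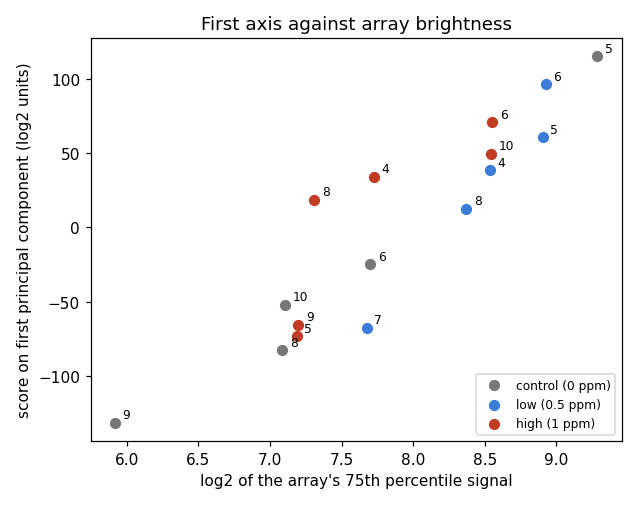
Score of each array on the first principal component (vertical axis, log2 units) against the log2 of its 75th percentile signal (horizontal axis); each point is 1 array, coloured by dose and numbered by replicate. Scores run from control replicate 9 at the lower left to control replicate 5 at the upper right, with r = 0.92 over the 16 arrays.

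The comparison of high dose with control asked which transcripts responded to 1 ppm arsenate. Transcript of per1, a repressor in the circadian clock, fell by 1.25 on the log2 scale (SE 0.19, limma adjusted p = 0.0387), a 2.38-fold difference. Its log2 signal was 2.06 ± 0.45 in controls (n = 5), 1.17 ± 0.22 at the low dose (n = 5) and 0.81 ± 0.15 at the high dose (n = 6, SD), and all 6 high-dose arrays lay below every control. Transcript of ch25h, which encodes cholesterol 25-hydroxylase, fell on 2 of its 4 probes, by 1.81 (SE 0.27) and 1.60 (SE 0.24, adjusted p = 0.0387 for each), with 6 of 6 arrays below every control on both. The probe representing ch25h, which has the highest mean signal, gave -0.77 (SE 0.21, adjusted p = 0.221) and the remaining probe -0.52 (SE 0.28, adjusted p = 0.505). A pair of probes without a gene symbol also fell, that of accession BC092552 by 3.17 (SE 0.40, adjusted p = 0.018) and that of BC121240 by 0.76 (SE 0.12, adjusted p = 0.0401). The BC092552 probe was well above background on 5 of 5 control, 3 of 5 low-dose and 1 of 6 high-dose arrays, so the size of its difference is uncertain. It was -0.98 with normexp, where the probe did not pass. The offset of 50 used with normexp lies within the range of median processed signals, 18.3 to 128 per array. How much of the smaller difference came from this offset was not tested.

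These 5 probes were all that passed among 26345, none of them higher. A limma p under 0.05 before adjustment was found for 2987 (1222 higher, 1765 lower), where 1317 is the average by chance. Probes moved together across arrays, so the chance count can lie far from that average. Within slides, per1 gave -1.53, -1.47, -0.40 and -1.30 on slides 1 to 4, and all 5 probes were lower on 4 of 4 slides. With slide as a block no probe passed: per1 gave -1.16 (adjusted p = 0.172), the ch25h probes -1.85 (0.101) and -1.66 (0.148), BC092552 -3.06 (0.101) and BC121240 -0.73 (0.371). Over all alternatives per1 passed in 12 of 33 (adjusted p from 0.000252 to 1.00), the ch25h probes in 11 of 32 each (0.00137 to 1.00 and 0.00183 to 1.00), BC092552 in 23 of 32 (0.000101 to 0.968) and BC121240 in 11 of 33 (0.00137 to 1.00). The count also moved with single arrays. It was 1740 (832 higher, 908 lower, all 5 included) without control replicate 5, 11 without high replicate 8 or 9, and 3 without low replicate 5 or 7. It was 1 without control replicate 6, low replicate 4, 6 or 8, or high replicate 4 or 10, and 0 without control replicate 8 or 10 or high replicate 5 or 6. Without control replicate 9 it was 6, of which 1 was among the 5.

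**Figure D2:**
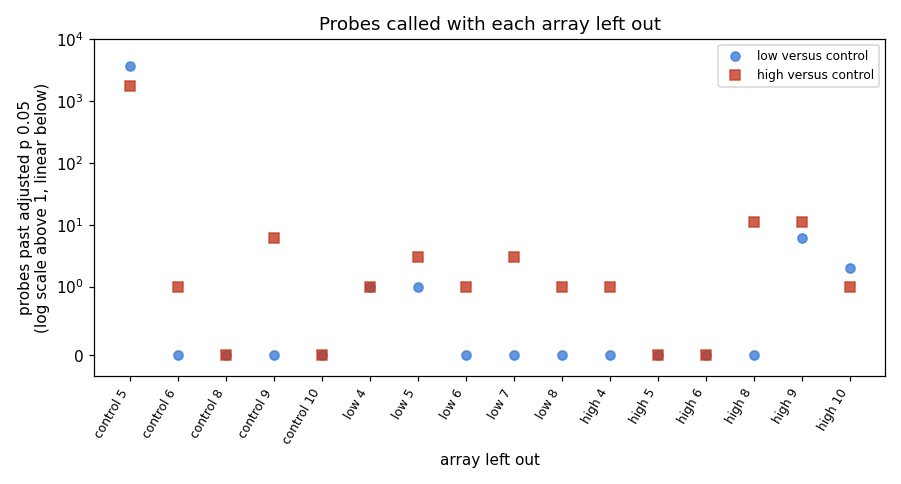
Number of probes past an adjusted p of 0.05 (vertical axis, log scale above 1 and linear below) with each array left out in turn (horizontal axis), for low against control (circles) and high against control (squares). Without control replicate 5 the counts are 3681 and 1740; without any other array they are at most 6 and 11.

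Several genes, among them single members of the stress lists, had small p at the high dose without passing over all probes. Values lower than control were given by hspa5, the endoplasmic reticulum chaperone BiP (-0.75, SE 0.17, adjusted p = 0.164), chac1, a glutathione-degrading enzyme of the integrated stress response (-1.04, SE 0.29, adjusted p = 0.221), and hspa1b, an inducible cytosolic chaperone (-2.25, SE 0.54, adjusted p = 0.176, well above background on 3 of 6 high-dose arrays). Controls of hspa1b spread widely (SD 1.55), the lowest at -4.53 against a high-dose mean of -4.14. Its differences on slides 1 to 4 were -2.72, -2.21, -4.19 and -0.285. The AP-1 subunit genes fosl1 (xhyb probe, -2.77, SE 0.52, adjusted p = 0.105) and junb (-0.68, SE 0.21, adjusted p = 0.235) and the kinase gene mknk2 (-0.92, SE 0.16, adjusted p = 0.0758) were also lower. In all of these 6 of 6 arrays were below the control mean. The aldehyde dehydrogenase gene aldh8a1 had a log2 signal of -1.46 ± 0.19 in controls and -2.46 ± 0.37 at the high dose (SD, adjusted p = 0.105), with 6 of 6 arrays below every control. Other values below control included lrrcc1 (-0.88), ube2ql1 (xhyb, -0.76), ncdn (-0.75), med1l (xhyb, -0.72), ranbp3l (-0.71) and ptcd2 (-0.68), with adjusted p of 0.120 to 0.173. Among values above control, serinc5 gave 2.82 times the control signal (adjusted p = 0.141), rhobtb1 a log2 value of 1.01 (SE 0.24), the proteoglycan gene cspg4 0.89 (SE 0.22) and dhx36 (xhyb) 0.92 (SE 0.21). The organic anion transporter gene slc22a8 gave 1.21 (SE 0.26) and the parathyroid hormone receptor gene pth1r 0.76 (SE 0.20), and these 2 values turned below 0 with normexp (-0.10 and -0.063). The values of hjv (0.97), edaradd (0.94), atp13a-like (0.83), fip1l1 (xhyb, 0.80), col8a2 (0.76) and nr2f5 (0.60) did not pass either. The oxidative stress indicator hmox1, haem oxygenase, gave 0.20 (SE 0.19, adjusted p = 0.702).

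**Figure D3:**
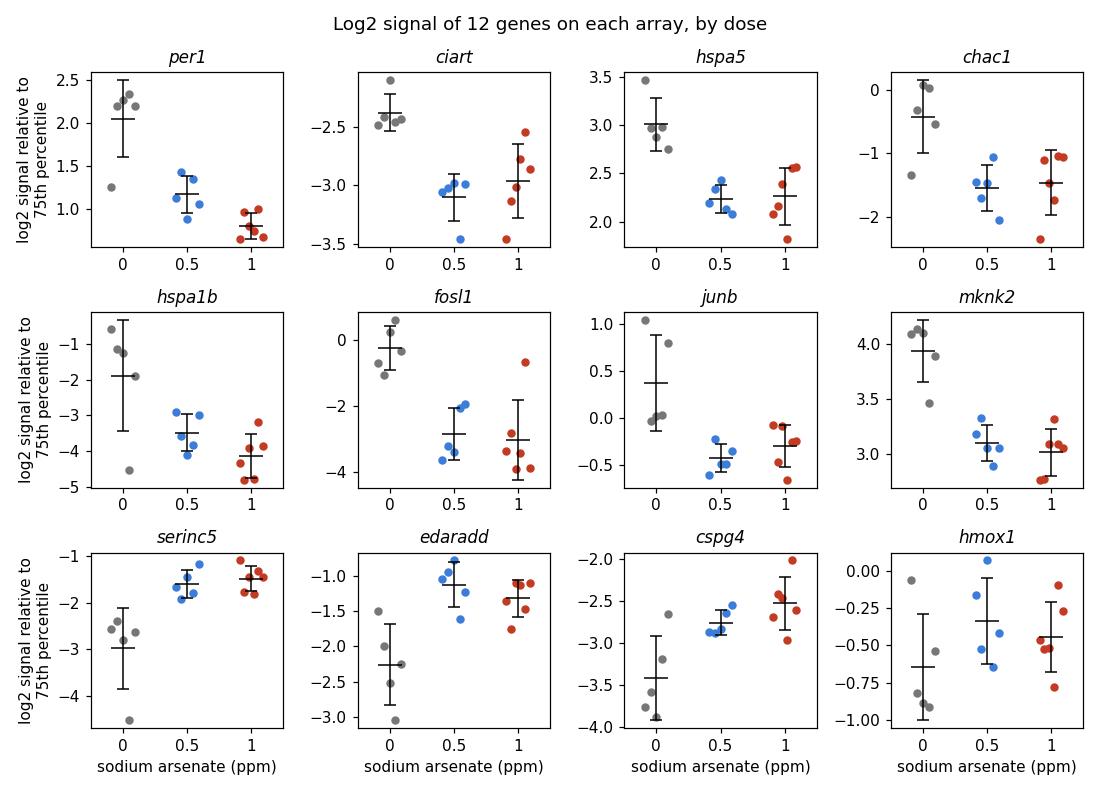
Log2 signal relative to the array's 75th percentile (vertical axes) of 12 genes at 0, 0.5 and 1 ppm sodium arsenate (horizontal axes); points are arrays, the long tick is the mean and the bars are the SD (n = 5, 5 and 6). The clock, chaperone and AP-1 genes have lower means and serinc5, edaradd and cspg4 higher means at both doses, but only per1 at the high dose passed the test over all probes, and serinc5 at the low dose turned below 0 with normexp (-0.053).

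By gene list, members of the unfolded protein and integrated stress response list were lower in 8 of 9 cases at the high dose (median -0.20, slide medians -0.15, -0.37, -0.52 and -0.23). None passed over all probes, and 2, hspa5 and chac1, passed when adjusted over the list alone. The list's camera test gave p = 0.00429 (adjusted p = 0.0815, and adjusted p = 0.206 with an estimated correlation). With slide as a block its median was -0.24 and it passed (adjusted p = 0.0158, and adjusted p = 0.113 with an estimated correlation). Of the 6 measured members of the circadian clock list, per1 and ciart, a repressor of the clock loop, passed when adjusted over the list alone, and per1 also over all probes. The ciart value was -0.59 (SE 0.17), and bhlhe40 (0.33), dbp (0.54), hlf (-0.12) and rorb (-0.21) passed neither. Further single members passing when adjusted over their list alone were hspa1b of 7 heat shock genes, fetub (-0.53) of 8 liver and plasma protein genes and fech (0.52), the last enzyme of haem synthesis, of 6 erythroid genes. Of the antioxidant and NRF2 targets, 4 of the 5 measured were above 0 (median 0.20) and none passed, nor did any of 6 metal-handling, 8 cell cycle or 13 lipid and sterol genes measured.

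Camera called 0 of the 19 lists at the high dose, with adjusted p from 0.0815 to 0.960, and 0 with an estimated correlation. It called 1, the unfolded protein list, without control replicate 8, 9 or 10 or high replicate 6 or 10, in each case lost with an estimated correlation (adjusted p from 0.0566 to 0.143). The directional fry test, which asks whether the genes of a list move on balance in a single direction and makes no comparison with other genes, called 4. These were the unfolded protein list (adjusted p = 0.00765) and the methionine and one-carbon (5 of 5 above 0, median 0.27), p53 and DNA damage (5 of 6 below 0, median -0.14) and circadian lists (4 of 6 below 0, median -0.16), each of these 3 at adjusted p = 0.0475. The mixed fry test called 0.

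The low dose against control addressed the response to 0.5 ppm. No probe passed with limma (smallest adjusted p = 0.0601), while 3533 had an unadjusted p under 0.05 (1842 higher, 1691 lower). The smallest p belonged to 2 probes of ch25h, at -1.96 (SE 0.28) and -1.67 (SE 0.25), with its other probes at -1.25 (SE 0.22) and -0.90 (SE 0.29), and all 5 low-dose arrays lay below every control on the first 3 of these. Values for mknk2 (-0.84, SE 0.17), fosl1 (-2.59, SE 0.55), per1 (-0.88, SE 0.20) and hspa5 (-0.77, SE 0.18) were also below control, with adjusted p of 0.205 to 0.296. Also below control were ciart (-0.72), junb (-0.81), chac1 (-1.13), med1l (-0.53), the complement protease gene c1s (-1.21, well above background on 3 of 5 control and 3 of 5 low-dose arrays), the centrosomal kinase gene nek2 (xhyb, -1.02), ifng (xhyb, -1.07) and hspa1b (-1.59). Each of these gave lower values on 4 of 4 slides, apart from hspa1b, which did not differ on slide 4.

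Values above control at the low dose were given by edaradd, an adaptor of the ectodysplasin receptor (1.13, SE 0.25), txndc12 of the endoplasmic reticulum (xhyb, 1.51, SE 0.38), the trafficking gene tmed2 (1.06, SE 0.27), the bicarbonate cotransporter gene slc4a4 (0.75, SE 0.19), rhobtb1 (0.92, SE 0.25) and col8a2 (0.79, SE 0.21), with adjusted p of 0.263 to 0.330. Those of serinc5 (1.38), otulinl (0.70), lexm (0.85), cxcl11 (0.95), neurl3 (xhyb, 1.03) and fam83d (0.60) turned below 0 with normexp, which moved the median of all probes to -0.32 from -0.061 and the share of probes above control to 30.6% from 44.7%. At the high dose the same change was to -0.11 from -0.019 and to 30.3% from 47.9%. The normexp offset of 50 was the same on arrays of every brightness, and its share in these changes was not tested. The value of hmox1 was 0.31 (SE 0.20, adjusted p = 0.451).

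When adjusted over the list alone, hspa5 and chac1 passed among 9 unfolded protein genes, per1 and ciart among 6 clock genes and slc4a4 among 10 pronephros genes at the low dose. The lipid and sterol list had 7 of 13 members above 0 (median 0.08), among them lpl (1.21) and apob (1.85), with unadjusted limma p of 0.0302 and 0.0278. The apob signal followed the first axis across all arrays (r = 0.92), so its value cannot be told apart from that axis. The heat shock list had a median of 0.05, a mean of -0.28 and a camera direction downward. Medians of the antioxidant (0.31, 3 of 5 above 0), methionine and one-carbon (0.11), cell cycle (0.23), lens and retina (0.27) and Hox (0.00) lists did not pass. Camera called 0 of 19 lists (adjusted p from 0.701 to 0.983), 0 with an estimated correlation. Directional fry called 1, the p53 and DNA damage list (4 of 6 below 0, median -0.18, adjusted p = 0.00713), whose member with the smallest p was xpc (-1.07, unadjusted p = 0.0495), and mixed fry called 0. Without control replicate 5 the number of probes past the threshold at the low dose was 3681 (2060 higher, 1621 lower). It was 6 without high replicate 9, 2 without high replicate 10, 1 without low replicate 4 or 5 and 0 without any other array.

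The high dose against the low dose tested whether the doses differed. No probe passed with limma (smallest adjusted p = 0.999), and 924 had an unadjusted p under 0.05, where 1317 is the average by chance. Values with the smallest p were higher at the high dose for hacd3 (xhyb, 0.82, SE 0.17), egflam (1.01, SE 0.28), apba1 (0.71, SE 0.21), kdm7a (xhyb, 0.87, SE 0.27) and the netrin receptor gene dcc (0.54, SE 0.17). They were lower for lrp2, the kidney endocytic receptor megalin (-0.41, SE 0.12), the metal exporter gene slc30a10 (-0.47, SE 0.14) and entpd5 (-0.48, SE 0.15). The probe of trmt12 (xhyb) was not well above background on any high-dose array. Given as a bound, it was 1.77-fold lower there than at the low dose, where 4 of 5 arrays measured it. The bound holds only for the main processing, since this difference and the value of mterf4 (-0.71) turned above 0 with normexp (0.48 for each). For per1 the difference was -0.37 (SE 0.19) and for hspa5 0.03 (SE 0.17). Adjusted over the list alone, slc30a10 passed among 6 metal-handling genes and lrp2 among 10 pronephros genes. Camera called 0 of 19 lists (adjusted p from 0.482 to 0.999), 0 with an estimated correlation, and fry called 0.

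A linear trend over 0, 0.5 and 1 ppm was tested in the same way, and no probe passed with limma (smallest adjusted p = 0.0522, 2765 with an unadjusted p under 0.05). The slope of per1 was -1.23 per ppm (SE 0.20, adjusted p = 0.108). The count was 8 without high replicate 9, and 1 without control replicate 5 or low replicate 4, 5, 7 or 8.

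The effects of both doses were compared across all 26345 probes, which are not independent replicates. The log2 fold changes of low and high dose against control correlated with r of 0.81 and had the same sign for 80.3% of probes. Simulated unchanged groups set against the same controls gave a median r of 0.60 (95% from -0.49 to 0.95), and 22.9% of 2000 simulations gave an r as large. The covariance was 0.150 against 0.0641 in the simulations, 12.1% of which gave one as large. With the controls divided between the 2 comparisons, r had a median of 0.38 over 20 divisions (-0.41 to 0.65), the covariance was 0.0827 and the same sign was found for 62.1% of probes.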

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

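Chosen only after their results were seen were the tests of other splits for the low-dose and high-dose counts and for the counts without control replicate 5 or with array weights, all tests of the dominant axis, and those of the 9 genes lower at both doses. In groups of 5 or 6 arrays, a value was singled out when its gap to the nearest other array was large against the range of its group; chance singles out about 1 in 20 groups, and 17 values were found among 177 groups.

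Control replicate 5 gave 4 of them, the lowest control signal of per1 (1.26), ptcd2 (-0.22) and lrrcc1 (-1.35) and the highest of cxcl11 (-3.20). High replicate 8 had the lowest score of its group on the second principal component (-44.4), the highest med1l (2.18) and the lowest col8a2 (-1.37). Control replicate 8 had the lowest mean log2 signal of the spike-in RNA in its group (11.3) and the highest ciart (-2.10), and low replicate 4 the lowest spike-in signal at the low dose (13.1). Control replicate 9 had the lowest control value of serinc5 (-4.51) and slc30a10 (0.95), and control replicate 10 the highest of dcc (-2.02). Low replicate 6 had the lowest ncdn (-0.53) and nek2 (-2.58) at the low dose, low replicate 7 the lowest ciart (-3.46), and high replicate 9 the highest fosl1 at the high dose (-0.68).

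Counts were set beside those of 100 splits of the same arrays into groups of the same sizes, the real split included. For high against control, 4 splits gave at least the real 5 probes, the highest other 9212. That share is under 5% for splits that leave slide aside. It rests on a sample of the possible splits and on a test chosen after the count was seen. Chance is therefore not firmly excluded, and with slide as a block no probe passed (limma adjusted p from 0.101 to 0.371 for the 5). Of the others, 3 splits gave over 100, which points to a structure of the arrays that can also give calls. Whether brightness accounts for the calls of those splits was not tested. With brightness as a covariate, per1 gave -1.16 at the high dose and passed. The real count was 0 for low against control (highest other 12705), high against low (highest other 3), the dose trend (highest other 389) and the lists called at the low dose (highest other 1), at the high dose (highest other 1) and between doses (highest other 2). All 100 of 100 splits reach 0, so they decide nothing there. For both doses pooled against control, 2 of 100 gave at least the real 22, the highest other 10698. This share is also under 5% for assignments that leave slide aside, while with slide as a block the count was 1.

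The first pattern weighed is the axis holding 60.1% of the variance (57.5% after quantile normalization, 58.2% in the deposited values). A distortion that depends on signal strength is argued against by the loadings, of which a probe's mean signal explained 9.41% of the variance. Scores spread over at least 123 units within every slide, against an SD of 72.4 over all arrays, which argues against slide as the main source. A smaller share of slide stays open, since a range tends to exceed an SD. Yield of labelling and scanning, as read by 7 spike-in probes, stays open: its relation to the axis had r = 0.38 (95% interval -0.14 to 0.74, permutation p = 0.146, adjusted p = 0.146 over 3 relations), rho = 0.41 (permutation p = 0.118), r = 0.36 without control replicate 8 and low replicate 4, and 0.21 within slides. Its relation to brightness had r = 0.43 (permutation p = 0.0924, adjusted p = 0.139), rho = 0.56 (permutation p = 0.0264), r = 0.62 without the same arrays, and 0.25 within slides. The amount or quality of RNA before the spike-in was added, and the stage of the embryos, stay open too.

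The second pattern is the rise of the counts when control replicate 5, the brightest array, is left out: 3681 probes at the low dose and 1740 at the high dose, of which 1192 were called at both, all in the same direction. This array was picked for its count, and when each of 100 splits was given the highest count over the 16 arrays left out in turn, 11 gave at least 3681 (highest other 13586) and 12 at least 1740 (highest other 11945), so chance cannot be excluded, and counts several times the real ones point to a structure of the arrays. At least 99.7% of the called probes differed in the direction of their loading on the axis, and with brightness as a covariate 0 and 13 calls were left. At the low dose the median size of the log2 fold change dropped from 1.01 (median SE of a single probe 0.27) to 0.34 (median SE 0.29). At the high dose it was 0.84 (median SE 0.20) and then 0.63 (median SE 0.19). Brightness and dose cannot be told apart for the calls of either dose. The other 4 controls had a mean log2 brightness of 6.95, against 8.48 and 7.75 in the exposed groups. Their mean score on the axis was -72.8, so the match with the loadings does not tell brightness and dose apart either. Array weights, which gave control replicate 5 the lowest weight (0.18), called 9785 and 8921 probes, and 5 of 30 splits gave as many in each case (highest others 13923 and 14777), so chance cannot be excluded there.

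The third pattern is the lower signal at both doses of 9 genes picked from the smallest p (hspa5, chac1, hspa1b, fosl1, junb, per1, ciart, mknk2 and ch25h), which form no list fixed beforehand. In the lists that hold some of them camera called none in the main setting, and other members lay above control at the high dose (hspa8 0.76, dbp 0.54, bhlhe40 0.33). At that dose camera called the unfolded protein list with slide as a block or brightness as a covariate (adjusted p = 0.0158 and 0.00371). With an estimated correlation only the call with brightness held (camera adjusted p = 0.113 and 0.0420). With brightness as a covariate the median of the 9 genes was -0.93 at the high dose, against -0.92 without it. At the low dose it was -0.97, against -0.88 without it. Every gene was still lower, by 3.61 SE at the high and 2.72 SE at the low dose for the weakest. With slide as a block the median was -0.86 at the high dose (3.00 SE for the weakest). These genes were picked for small p in a fit without brightness or slide. That choice passes over genes that vary much with either inside the groups, so these values cannot exclude brightness or slide. Low-dose values shrank with brightness as a covariate for per1 (-0.88 to -0.60), chac1 (-1.13 to -0.80), ch25h (-1.25 to -0.92) and fosl1 (-2.59 to -1.87). They grew or held for hspa5 (-0.77 to -0.97), hspa1b (-1.59 to -2.39), junb (-0.81 to -1.06), mknk2 (-0.84 to -0.99) and ciart (-0.72 to -0.73). With this covariate 1 of the 9 passed at the low dose and 5 at the high dose. A different clock time of collection may lower clock genes. The other 4 measured clock genes had a median size of 0.27 (median SE of a single gene 0.32), which leaves it open. Handling or collection of the control embryos and arsenate itself are also open and were not tested. Chance in the picking of the genes stays open too and was not tested, since both comparisons use the same controls. Simulated unchanged groups sharing the controls gave a median r of 0.60 between the effects of both doses. Lower values at both doses are therefore partly built in.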

How the results depend on the processing

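Added after the data were seen were brightness as a covariate, the omission of controls 5 and 9 together, the omission of control 5 with brightness as a covariate, and probes named specific alone; the cause of a change was not tested unless stated. Of 2446 values of named genes under alternatives, 2171 kept their direction and side of the threshold, 94 lost and 148 gained a call, and 33 changed sign. Only the 5 probes called at the high dose had a call to lose. Their calls held in 12 of 33 alternatives for per1, 11 of 32 for each ch25h probe, 23 of 32 for BC092552 and 11 of 33 for BC121240. The per1 value at the high dose lay between -1.46 and -0.85 over alternatives that of BC092552 between -3.38 and -0.98, those of the ch25h probes between -1.96 and -0.66 and between -1.79 and -0.66, and that of BC121240 between -0.80 and -0.45.

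The number of probes at the high dose (5) became 0 with normexp, quantile normalization, slide as a fixed block or array position as a block, 1 with no filter on dim probes, only the 2 groups compared or a single probe per gene (fewer probes tested), 2 with median scaling or the filter on all 16 arrays, and 11 with the deposited values or eBayes with trend and robust. At adjusted p 0.10 it was 15, at unadjusted p 0.05 with a 2-fold change 192, with array weights 8921, with brightness 195, without controls 5 and 9 65, and without control 5 and with brightness 13. At the low dose (0) it was 1 with quantile normalization or the deposited values, 2 at adjusted p 0.10 or with specific probes, 620 at unadjusted p 0.05 with a 2-fold change, 9785 with array weights, 9 with brightness and 90 without controls 5 and 9. Between doses (0) it was 30 at unadjusted p 0.05 with a 2-fold change. The trend (0) gave 2 with median scaling, 1 at adjusted p 0.10, with eBayes trend and robust, a single probe per gene, specific probes, or without control 5 and with brightness, 5433 with array weights and 186 with brightness. Lists called became 1 in each comparison with normexp (cartilage and extracellular matrix; with an estimated correlation adjusted p = 0.274, 0.263 and 0.349), and 1 at the high dose (the unfolded protein list) with the deposited values, slide as a fixed block or brightness (with an estimated correlation adjusted p = 0.201, 0.113 and 0.0420, so that the call holds with brightness alone). With directional fry they became 1 at the low and 4 at the high dose. The correlation of low and high effects was 0.38 with controls split.

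Leaving out each array in turn gave 0 to 3681 probes at the low dose, 0 to 1740 at the high dose, 0 to 0 between doses and 0 to 8 for the trend, 0 to 0, 0 to 1 and 0 to 0 lists, and a correlation of 0.72 to 0.91. Whole-array deviations showed no pairing by replicate number. The 12 pairs of equal number had deviations correlated from -0.85 to 0.74 (median 0.035, against -0.050 for other pairs), 5 above 0.1, and 1 of 15 arrays correlated best with its own number. The first axis, which held 60.1% of the variance, weighs heavily in such deviations, so a smaller effect shared by equal numbers could be hidden. With the replicate block, 1 probe passed at the high dose and 1 for the trend, and with the replicate block and slide 0 at the high dose.

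Signs turned with normexp at the low dose for fam83d (-0.20), serinc5 (-0.053), cxcl11 (-0.55), otulinl (-0.097), lexm (-0.44) and neurl3 (-0.67), at the high dose for slc22a8 (-0.10) and pth1r (-0.063), and between doses for hspa5 (-0.17), mterf4 (0.48), hmox1 (0.0037), trmt12 (0.48) and BC092552 (0.33). Between doses hspa5 turned with median scaling (-0.067), the replicate block (-0.045), the replicate block and slide (-0.0064), and without high replicate 10 (-0.035), 6 (-0.00047) or 9 (-0.032) or low replicate 8 (-0.012), and reached 0.11 without high replicate 8. The second ch25h probe turned with median scaling (-0.018), the deposited values (-0.043), slide as a block (-0.0082), the replicate block (-0.043), that and slide (-0.19), array weights (-0.21), and without low replicate 7 (-0.054) or high replicate 9 (-0.025), and reached 0.22 without high replicate 10. The first ch25h probe turned with the replicate block (-0.0088), that and slide (-0.14), array weights (-0.27) and without low replicate 7 (-0.00085), and reached 0.32 without low replicate 5. The sign of hmox1 also turned with brightness (0.049). Signal over background limits slc22a8, neurl3, trmt12, BC092552, hspa1b, c1s, mterf4 and cxcl11, which were well above background on few arrays of some groups.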

Other observations

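All of the tests below were chosen only after the data were seen, apart from the gene lists themselves. Pooling the doses against control, 22 probes passed with limma, 4 higher and 18 lower. Besides ch25h (-1.88, SE 0.24, and -1.63, SE 0.21, adjusted p = 0.00781 for each) and per1 (-1.07, SE 0.17, adjusted p = 0.0403), these included the kinase gene mknk2, which fell by 0.88 (SE 0.14, adjusted p = 0.0403), and fosl1 (xhyb probe), which fell by 2.68 (SE 0.47, adjusted p = 0.0403). For mknk2 the log2 signal was 3.94 ± 0.28 in controls, 3.10 ± 0.16 at the low dose and 3.01 ± 0.21 at the high dose (SD), with 5 of 5 and 6 of 6 arrays below every control. For fosl1 it was -0.25 ± 0.67, -2.85 ± 0.79 and -3.02 ± 1.21, with 5 of 5 and 5 of 6 arrays below every control. The 22 are probes and not separate genes, since 2 of them belong to ch25h. Some called probes without a symbol had group means near those of fosl1. A set of 4 probes, that of fosl1 among them, correlated with r of 0.976 to 0.992 over the 16 arrays. Whether such probes measure the same transcript was not tested. The count was 5437 without control replicate 5, 41 without high replicate 8, 20 without high replicate 9, 10 without control replicate 9 or low replicate 7, 5 without control replicate 6, 3 without low replicate 4, 5, 6 or 8 or high replicate 4, 5, 6 or 10, 2 without control replicate 8 and 0 without control replicate 10, and 1 with slide as a fixed block.

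With brightness as a covariate, per1 (-1.16), mknk2 (-0.97), fosl1 (-2.54), hspa1b (2 of 6 high-dose arrays below every control) and hspa5 (-0.81) passed at the high dose, and at the low dose mknk2 did (-0.99).

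A hypothesis for the dominant axis, formed from the crystallin, cpa1 and apob genes seen at its high end, is that embryos differed in developmental progress between arrays. The test took the lens and retina, liver and plasma protein, and exocrine pancreas and gut lists without crystallins and without genes seen at the ends of the axis. The median loading of the 16 members left stood at percentile 78.57 of 10000 random lists matched on mean signal, with 8 of 16 loadings above 0; alone, the 3 lists stood at percentiles 78.46, 35.46 and 84.78. The 6 members left of the gastrula and maternal lists (nog, sox2, hes5.10, dnd1, grip2 and h1-8) stood at percentile 6.01, with 0 of 6 loadings above 0. Beyond the genes that prompted it, the hypothesis is therefore neither borne out nor excluded.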
